A study of Homo sapiens with 2 samples.

How the data were processed

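Crosslink sites of hnRNPM were measured by iCLIP in HMLE cells, a human mammary epithelial line, in 2 libraries labelled as biological replicates of wild-type cells given DMSO. Per the labels' protocols, the cells were crosslinked with ultraviolet light and precipitated with an antibody against hnRNPM. The genome build was GRCh37, per the submitters' processing notes. The aligner, the site caller, their settings, the treatment of PCR duplicates and the annotation were not given in the sources used here.

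The deposited file was a list of 54373 intervals of 21 nt. The score deposited by the authors for each interval was a whole number, named here the height, and it equalled the value marked PH in the name of the site. The name opened with CITS and a running number. It also held a tag cluster with its strand, a value marked PH0 and a value marked P, all as the authors deposited them. The file does not define them: PH was read as the number of truncation events at the site and PH0 as the number expected from the level of the tag cluster, since PH0 had 1 value per cluster. The P values deposited by the authors ran from 1e-100, the value of 8814 sites, to 9.99e-04. The tallest site did not have the smallest P (its value was 8.41e-11), so sites were ranked by height. The running numbers reached 224765, and the numbers present made up 24.2% of that range. The list had 1 height per site and named no library. It was taken as pooled over both libraries, which the sources used here do not state, so leaving out a replicate, comparing replicates and stating a depth per library were not possible. Intervals and p-values given here describe the scatter of sites along the genome and not the spread between cultures.

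The annotation at hand was GENCODE release 29 on GRCh38, without a genome sequence. On 13 of 23 chromosomes a site lay beyond the last annotated GRCh38 gene, and no position was compared between the builds. The planned measures that need GRCh37 genes or sequence were therefore not run: distance to the next site against redraws within genes, sense share, intronic and deep intronic shares, GU-rich motif enrichment, soft-masked repeat and LINE-1 shares, gene list binding, and the relation of gene length to site number. For the same reason no gene is named. The annotation gave totals per chromosome: 1208 Mb of intron and 101 Mb of exon of protein-coding genes, the number of these genes and the last gene end. It also gave the share of coding gene length overlapped by a coding gene on the other strand, which was 3.53%.

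The naming rule, fixed before the data were examined, took the 10 sites of best score and, without an annotation of the build, the 5 regions of 100 kb with the most sites. Positions are 1-based. The test of shared strand between neighbours, fixed before the data were examined, permuted strands among the sites of a chromosome 1000 times. All other tests were chosen after seeing the data. Stretches were sites of 1 strand with gaps of at most 50 kb. Their inner sites were redrawn evenly between the first and last site, with the smallest gap kept, 1000 times. Close pairs were compared with 1000 sets in which each site was redrawn in its own fixed window of 5 kb. Opposite strands were compared with 1000 shifts of all minus-strand sites by 20 to 200 kb. Neighbours were counted within 1 kb, and pairs of equal height were left out of the comparison of upstream and downstream sites. Intervals are 95% percentile intervals from 1000 bootstrap draws over 1-Mb bins, or 200 draws for the correlation of height with neighbours, and 10000 draws over chromosomes for differences of correlations. Alternatives of the share of sites in stretches were judged by a Wilson binomial interval over sites. Permutation tests used 100000 resamples except where 1000 or 100 are stated, and they were two-sided.

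Other settings fixed before the data were examined were the better-scoring sites (the upper 50% by height), sites of 1 strand within 50 nt merged, and only sites at least 5 nt wide. Further settings, chosen after seeing the data, were other stretch gaps, windows and limits, removal of the expected height, and annotated genes of all types. The statistics were tested on simulated data made from the 54373 sites. Redrawn sets gave p under 0.05 for the share at 26 to 50 nt in 5.4% of 1000 sets; smaller runs had given 5 of 40 and 18 of 200 sets. A first reference for this share, with each site moved by up to 2.5 kb, was given up because it found a ratio of 1.19 (permutation p = 0.0099) in data with no excess. Of 2000 close pairs added, 1872 were recovered above the redrawn mean. Where the upstream site was made the taller one in 70.5% of close pairs, 69.3% was recovered. With permuted heights, 51.5% was found. Strands set in 1-Mb blocks gave the planted 96.7% of same-strand pairs. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.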

Results

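The binding of hnRNPM, an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein family that takes part in splicing, was mapped in HMLE cells by iCLIP. HMLE is an established line of immortalised human mammary epithelial cells. In iCLIP, ultraviolet light crosslinks a protein to the RNA it touches, the protein is precipitated with an antibody, and reverse transcription often stops at the crosslinked base, so that pile-ups of such stops mark binding positions. There were 2 libraries, labelled as biological replicates 1 and 2 of wild-type cells given DMSO, and they formed 1 group. The series asked where hnRNPM binds in these cells, in a study of splicing linked to LINE repeats. The deposited result was 1 list of crosslink sites with no value per library. No spread between replicates could therefore be given, the depth of each library is unknown here, and there was no second group to compare. No RNA level was set beside the sites, so heights and site numbers were not corrected for RNA abundance and do not rank binding strength.

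The list held 54373 sites on 22 autosomes and chromosome X, each 21 nt wide, with 27858 on the plus strand and 26515 on the minus strand (51.2% plus). Each site carried the authors' height. The median height was 11, with quartiles of 8 and 17 and a range of 4 to 1969. Tall sites were few: 192 sites reached a height of 100, and the tallest 1% (544 sites) held 8.11% of the summed height of 854261. Each site also carried the authors' expected height, with a median of 0.51, and the median ratio of height to expected height was 23.7 (quartiles 18.3 and 30.6). The sites fell into 40129 of the authors' tag clusters, of which 30778 (76.7%) held 1 site and the fullest held 12.

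The tallest sites lay almost entirely in a short part of chromosome 11. Of the 10 tallest sites, 9 were on the plus strand of chromosome 11, in 2 tag clusters with 60.6 kb between their nearest sites (GRCh37). The 12 sites of the first cluster ran from 65192097 to 65206589, with heights from 149 to 1969 and a median of 604. These 12 sites made up 1.10% of the summed height of the whole list. The 2 sites of the second cluster ran from 65267142 to 65268438, with heights of 722 and 1949. The remaining site, on the minus strand of chromosome 2 from 133012872 to 133012892, had a height of 976. Its tag cluster held 1 more site, with a height of 220. The tallest site of all, on chromosome 11 from 65199405 to 65199425, was 61.2 times its expected height, against 31.7 times for the tallest site of the second cluster. Genes, exons and introns at these positions were not analysed here, because the annotation used was on another genome build.

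**Figure D1:**
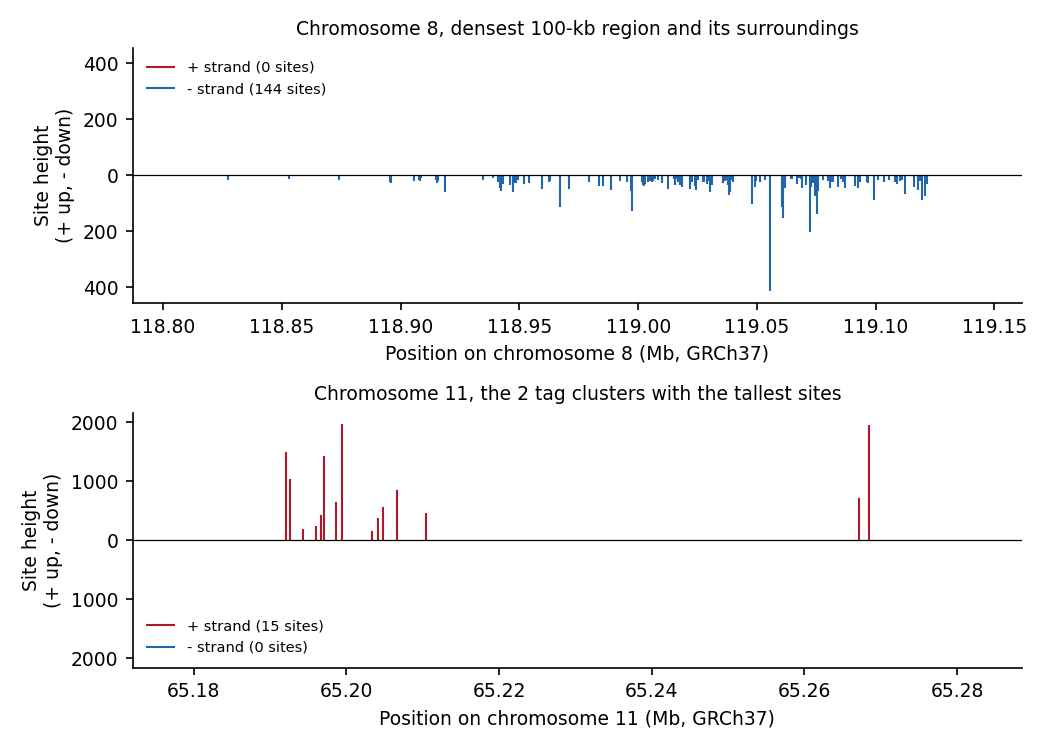
Site heights along chromosome 8 (upper panel) and chromosome 11 (lower panel), with position in Mb (GRCh37) on the horizontal axis and each line a site, drawn upwards for the plus strand and downwards for the minus strand. The 144 sites of the chromosome 8 stretch lie on the minus strand, and the lines of chromosome 11, the 2 tag clusters and 1 further site between them, lie on the plus strand and reach 1969.

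Many sites were gathered in regions that lay on 1 strand. The 100-kb region with the most sites, on chromosome 8 from 119000001 to 119100000, held 87 sites, all on the minus strand, with a median height of 25 and a tallest site of 414. It was followed by chromosome 2 from 153200001 to 153300000 with 81 sites, all on the plus strand and with a median height of 18. Chromosome 1 from 243900001 to 244000000 and chromosome 8 from 131300001 to 131400000 each held 64 sites, all on the minus strand. Chromosome 15 from 99200001 to 99300000 held 59 sites on the plus strand, a number that 3 regions shared. Sites were found in 7817 regions, with a median of 4 per region, and 1310 regions held 50% of all sites. Of the 1844 regions with at least 10 sites, 1688 (91.5%) had every site on the same strand. The ranking depended on where the regions began: after a shift by 50 kb, only 2 of the 5 regions overlapped 1 of the 5 densest, and the highest number was 79.

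Neighbouring sites shared a strand far more often than sites with shuffled strands. Of 54350 adjacent pairs, 94.6% were on the same strand (95% interval 94.3 to 94.8, bootstrap over 1-Mb bins), against a mean of 50.5% when strands were permuted within chromosomes. The two-sided permutation p was 0.001, the smallest that 1000 draws can give. All 23 chromosomes lay above the highest permuted value for the whole list, 51.2%; chromosome 19 was lowest at 89.9% and chromosome 8 highest at 95.6%. The share fell with distance. It was 100% for the 20030 pairs under 1 kb apart, 99.8% from 1 to 10 kb, 93.3% from 10 to 50 kb and 70.6% from 50 to 100 kb. From 100 to 500 kb it was 53.9%, and 52.2% beyond 500 kb. Pairs within 1 tag cluster share a strand by construction, since each cluster carries 1 strand, and the permutation did not keep clusters together. Of same-strand pairs at 800 to 999 nt, 36.1% lay in 1 cluster, and more did in every class of shorter gaps. At 1000 to 1499 nt the share in 1 cluster was 18.6%. The values at short gaps were thus partly fixed in advance.

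**Figure D2:**
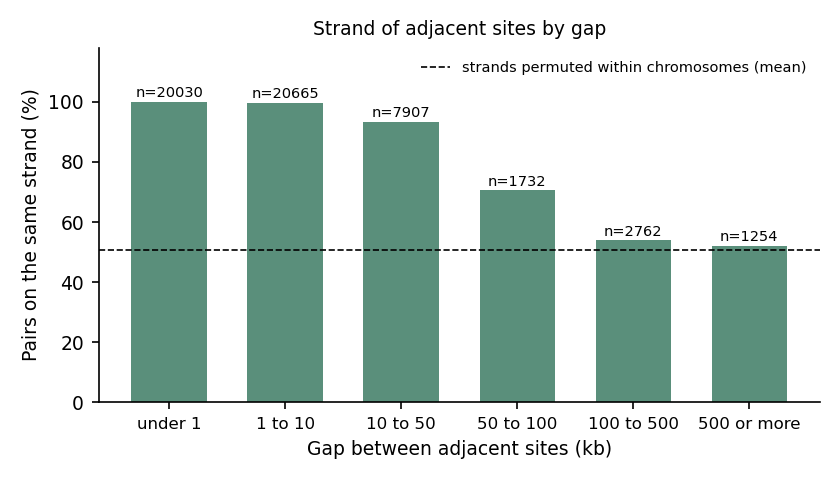
Percentage of adjacent sites on the same strand (vertical axis, bars from 0) by the gap between them in kb (horizontal axis), with the number of pairs above each bar and the mean of permuted strands as a dashed line. The bars fall from 100% under 1 kb to 52.2% at 500 kb or more, against 50.5% for permuted strands.

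Sites formed long stretches on 1 strand. A stretch was defined, after the data were seen, as sites of 1 strand with no site of the other strand between them and gaps of at most 50 kb. There were 6345 stretches, and the 1632 with at least 10 sites held 72.0% of all sites. With permuted strands such stretches held 0.82% of sites on average and 1.23% at most (permutation p = 0.0099, the smallest that 100 draws can give). Here too the permutation did not keep tag clusters together. These 1632 stretches had a median span of 84.6 kb (quartiles 54.0 and 131 kb). The stretch with the most sites, on the minus strand of chromosome 1 from 246053100 to 246716619, held 147 sites over 664 kb. The next, on the minus strand of chromosome 8 from 118827407 to 119121448, held 144 sites over 294 kb and included the region with the most sites.

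Where the strand changed between neighbours, the gap depended on the direction of the change. The 1480 divergent pairs (minus strand followed by plus) had a median gap of 138 kb, and the 1476 convergent pairs (plus followed by minus) one of 190 kb. The ratio of the medians was 1.37 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Within 20 kb there were 117 divergent and 61 convergent pairs. The closest sites on opposite strands were 1557 nt apart. None of the 27858 plus-strand sites had a minus-strand site within 1 kb, against a mean of 293 (range 62 to 544) when the minus-strand sites were shifted together by 20 to 200 kb (permutation p = 0.001, the smallest that 1000 shifts can give). Within 5 kb there were 31 such sites, against a mean of 895. Both windows were chosen after the data were seen.

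Within stretches, sites were unevenly spaced. The median gap was 1420 nt (95% interval 1384 to 1462), and it was 2885 nt when the inner sites of each stretch were redrawn evenly. The ratio was 0.492 (two-sided permutation p = 0.001, the smallest that 1000 redraws can give). Long gaps were in excess too: the class of longest gaps, which ended at 50 kb, was 2.63 times as frequent as in the redraws, and those of 3200 to under 6400 nt 0.530 times. The gaps had 2 ranges in which pairs were frequent, with a low between them. There were 182 pairs per nt of gap at 26 to 29 nt, where 26 nt was the smallest gap in the list, 8.80 at 80 to 99 nt and 24.3 at 300 to 349 nt. Whether the site caller set the smallest gap of 26 nt was not tested. In 5.37% of sites the next site on the strand was 26 to 50 nt away, against a mean of 0.971% when sites were redrawn within windows of 5 kb (5.53 times, permutation p = 0.001). The size of this excess depended on the redraw, since sites redrawn in windows can lie closer than the smallest gap of the list. The mean was 1.97% when redrawn pairs of 0 to 50 nt were all counted, and the even redraw within stretches, which kept the smallest gap, gave a ratio of 8.17 for 26 to under 50 nt. From 51 to 100 nt the direction itself depended on the redraw. The share was 1.40% against 1.89% in windows (0.743 times, permutation p = 0.001), while within stretches 1.64% of gaps were of 50 to under 100 nt against 1.38% redrawn (1.19 times). Both sites of every pair at 26 to 59 nt lay in the same tag cluster, against 70.1% of pairs at 300 to 349 nt. The planned redraw within genes was not run, and the distances were chosen after the data were seen.

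In the closest pairs the site upstream on the transcript was usually the taller one. Of the 2900 pairs of unequal height 26 to 59 nt apart, 1899 (65.5%, 95% interval 63.8 to 67.1) had the taller site upstream. The share was 67.2% on the plus strand and 63.7% on the minus strand. It was 57.3% (52.3 to 61.7) at 60 to 99 nt, 50.9% (48.5 to 53.3) at 100 to 199 nt and 48.0% (47.2 to 48.7) at 200 to under 1000 nt. The closest pairs exceeded those at 200 to under 1000 nt by 17.5 percentage points (15.7 to 19.3; two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The median heights of the upstream and downstream sites of the closest pairs were 14 and 12. These distances too were chosen after the data were seen.

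**Figure D3:**
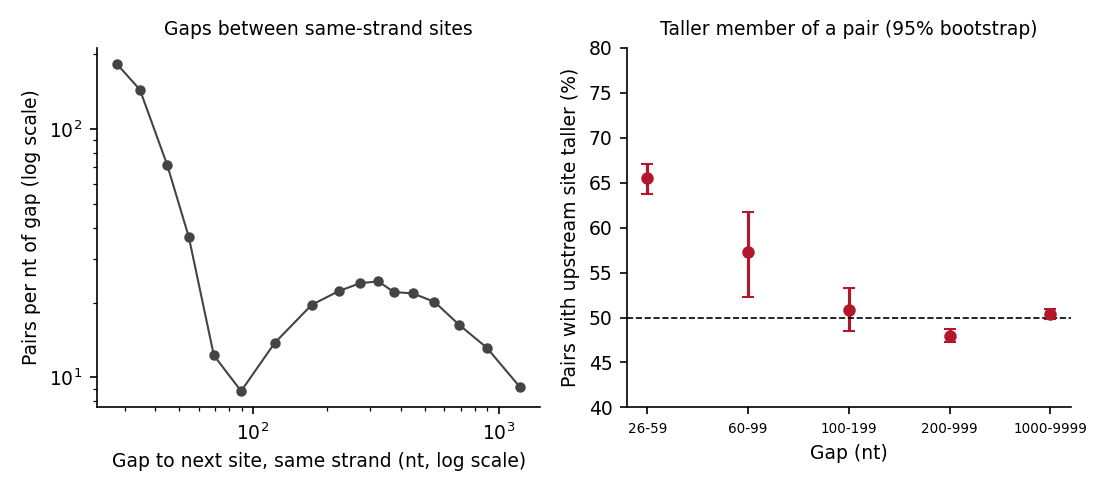
Left, pairs of neighbouring sites on 1 strand per nt of gap, against the gap in nt, both on log scales; the points fall from 182 to 8.80 and reach 24.3 at 300 to 349 nt. Right, percentage of pairs of unequal height with the taller site upstream, by gap in nt, with 95% bootstrap intervals and a dashed line at 50%; the share is 65.5% at 26 to 59 nt and 48.0% at 200 to under 1000 nt.

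Sites with more neighbours were taller. The 23231 sites with no other site of the strand within 1 kb had a median height of 10, and the 847 sites with 5 or more had one of 18. Across sites, which are not independent replicates, Spearman's rho between height and the number of neighbours was 0.314 (95% interval 0.304 to 0.324, bootstrap over 1-Mb bins). The median expected height rose alongside, from 0.38 to 1.08. Once the expected height was removed, rho was -0.089, and for the ratio of height to expected height it was -0.310. The expected height had 1 value per tag cluster and itself correlated with height at a rho of 0.793, so these values are not a separate measure of the relation.

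The number of sites per chromosome followed the length of introns more closely than that of exons. Across the 23 chromosomes, sites correlated with the total intron length of protein-coding genes at r = 0.971 (Spearman's rho 0.958; permutation p = 1e-05 for both, the smallest that 100000 resamples can give). Without chromosomes 1 and 2, which lie farthest from the median, r was 0.958. The correlation was 0.765 with exon length (rho 0.696, permutation p = 4e-05 and 0.00044) and 0.620 with the number of coding genes (rho 0.584, p = 0.00135 and 0.00373). The first was 0.586 without chromosomes 1 and 2, and the second 0.702 without chromosomes 1 and 19, the farthest from the median in gene number. With the extent of the chromosome r was 0.934 (rho 0.905, p = 1e-05 for both), and 0.888 without chromosomes 1 and 2. These were 4 relations of 1 family, and the adjusted p (Benjamini-Hochberg) for r was 2.0e-05 for intron length and extent, 5.3e-05 for exon length and 0.00135 for gene number. For rho, the adjusted p was 2.0e-05, 2.0e-05, 5.9e-04 and 0.00373 in the same order. The correlation with intron length exceeded that with exon length by 0.206 (95% interval 0.054 to 0.544) and that with gene number by 0.351 (0.102 to 0.811). It was not distinguishable from that with the extent of the chromosome (difference 0.037, interval -0.006 to 0.127). Without chromosomes 19 and X, r with intron length was 0.981, and the exon correlation was not recomputed. Chromosome 19 had 5.87 Mb of exon and 824 sites, while chromosome 11, with 5.92 Mb of exon, had 2619 sites. Part of the difference from exon length may therefore rest on chromosome 19, and how much was not computed. The lengths came from a GRCh38 annotation and the sites from GRCh37, so only totals per chromosome were set against each other. Intron made up 92.3% of the length of coding genes, so intron length could not be told apart from gene length here. Whether the sites themselves lay in introns was not measured.

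Chromosomes 19 and X had the fewest sites for their intron length. The whole list held 45.0 sites per Mb of intron. Chromosome 19 had 29.4 (95% interval 23.4 to 35.6) and chromosome X 30.01 (22.2 to 38.1), and the other 21 chromosomes lay between 39.5 and 55.8. Both also had fewer of their running numbers present than the whole list. Scaled to the share of the whole list, their intervals include the lowest other chromosome, at 38.7 (values below). Per protein-coding gene, chromosome 19 had 0.56 sites, against 2.74 in the whole list. Chromosome X, with 1.65, did not stand apart on this measure, since chromosome 17 had 1.58. The pair was singled out after the values were seen.

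**Figure D4:**
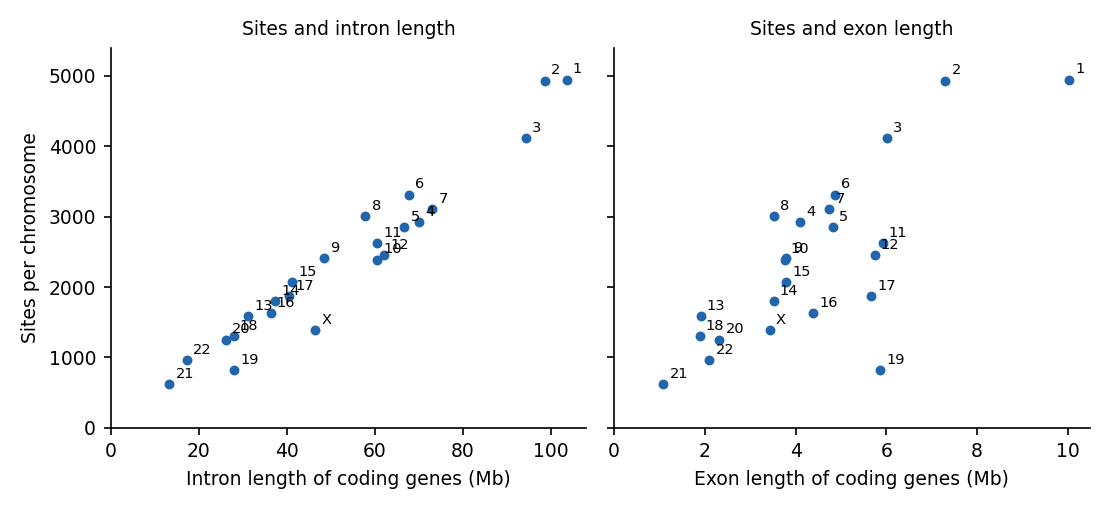
Number of sites on each of 23 chromosomes (vertical axis) against the total intron length (left) and exon length (right) of its protein-coding genes in Mb, each point a chromosome with its name. Points follow intron length at r = 0.971 and exon length at r = 0.765, and chromosomes 19 and X lie low for their intron length.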

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

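The alternatives planned before the data were examined were those for the number of sites and for the shared strand of neighbours; the others were chosen after seeing the data. Of 27 alternative values with a test, 26 kept their direction and their side of the threshold. Among them were distances of 20 and 100 kb for the isolated tall sites, which gave the same 9 sites and so repeated the reported values. Of 13 counts of sites, 12 stayed within 1.5 times the reported count, among them the list limited to sites at least 5 nt wide, which could remove none. Of 13 values without a test, only 1 stayed within the 95% interval of the reported value. For the share of sites in stretches this was a binomial interval over sites, which are not independent, so it is too narrow. The number of sites was 27187 in the better-scoring part of the list, by the construction of that alternative. Neighbours shared a strand in 92.7% of pairs there, and in 94.3% with close sites merged. The share of sites in stretches of at least 10 ranged from 56.8% with gaps of at most 20 kb to 77.7% with 100 kb. The share of close pairs with the upstream site taller ranged from 63.7% to 67.2%. The correlation of height with the number of neighbours ranged from 0.218 to 0.386 over other windows and the better-scoring sites, and it reversed to -0.089 after removal of the expected height and to -0.310 for height over expected height. Expected height follows the same tag cluster, so part of that may be by construction; the cause was not tested. The close-pair references moved with the redraw, as given with those shares. The expected height of isolated tall sites lost its call at a height of at least 150 (permutation p = 0.17), where 5 sites remained. No paired analysis was possible because the list is of 1 group with no value per library, and for the same reason no replicate was left out. The planned measures on genes, introns, motifs, repeats, LINE-1, gene lists and gene length, and the distances redrawn within genes, were not run without a GRCh37 genome and annotation. Library depth is unknown here, so how far low sites were missed cannot be stated.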

Other observations

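All tests below were chosen only after the results they measure were seen, with their limits. The design, with 1 group, offered no contrast of conditions in which to test a biological explanation.

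A few tall sites stood alone. Of the 192 sites with a height of at least 100, 9 (4.69%) had no other site of the strand within 50 kb, against 15 of 2220 (0.676%) with a height of 40 to 99 (Fisher's exact test, p = 4.9e-05). The share was 5.78% at heights of 4 to 9, 1.56% at 10 to 19 and 0.740% at 20 to 39. Against all other sites together (1572 of 54181, 2.90%) no difference was detectable (Fisher's exact test, p = 0.13), so the contrast is with sites of middle height and not with the list as a whole. It also rests on the limit: 13 of 458 sites (2.84%) with a height of at least 75 stood alone, and 5 of 75 (6.67%) with at least 150. The tallest lay on the minus strand of chromosome 1 from 91852849 to 91852869 with a height of 399, followed by chromosome 8 from 70602466 to 70602486 with 328 and chromosome 19 from 54971454 to 54971474, on the plus strand, with 274.

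A candidate explanation for these 9 sites is a short abundant or multicopy RNA, which would raise the level of the whole tag cluster. Their expected height was higher than at the other 183 sites by 1.10 on the log2 scale (permutation p = 0.016, adjusted over 3 comparisons 0.028), and 1.25 with p = 0.17 at a height of at least 150. Sites were permuted singly, although expected height has 1 value per tag cluster. Among the other 183 sites, 12 lay in 1 cluster on chromosome 11 and shared an expected height of 32.16, so the p-values are approximate. A pile-up at 1 position over a thin tag cluster would give a larger ratio of height to expected height. The log2 difference of this ratio was -0.70 (permutation p = 0.022, adjusted 0.028). The ratio is taken over the expected height already compared above, so it is not a separate measure. It therefore does not decide between such a pile-up and a short abundant or multicopy RNA. The isolated sites were also taller (median 192 against 135, permutation p = 0.028, adjusted 0.028), which alone may raise their expected height. Multicopy sequence was not analysed here, so a short abundant or multicopy RNA stays a hypothesis. A pile-up at 1 position stays open beside it.

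The absence of minus-strand sites within 1 kb of plus-strand sites was set against chance. Independent placement of the strands gave 293 such sites on average and at least 62 in every shift. The number of adjacent opposite-strand pairs already fell towards short gaps, from 13 per kb at 10 to 20 kb to 6.2 at 5 to 10 kb and 4.25 at 1 to 5 kb, so nothing particular to 1 kb is shown. Selection of sites by annotated strand before deposit was not tested and stays open, beside a separation of the transcribed strands themselves.

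The share of pairs 26 to 59 nt apart with the taller site upstream was set against that at 200 to under 1000 nt, and it was 17.5 percentage points higher. The reference share, 48.0%, itself lay below 50%, and 65.5% (63.8 to 67.1) lay above it. All of the closest pairs lay in 1 tag cluster, against 71.4% of pairs at 200 to 249 nt and 36.1% at 800 to 999 nt. The comparison thus differs in more than distance and restates the pattern, so it does not decide whether the sites are independent. A trend along the chromosome would turn on the minus strand, where the share was 63.7%, still above 50%. Read-through, cDNA length and the site caller were not tested, and each may give a lower second site downstream in 1 tag cluster. These stay open beside an ordered binding on the RNA.

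On chromosomes 19 and X, 21.2% and 20.1% of the running numbers were present, against 24.2% in the whole list; chromosome 21, with 21.6% present, had 46.5 sites per Mb of intron. At the share of the whole list, chromosome 19 would have 33.5 sites per Mb of intron (26.7 to 40.6) and chromosome X 36.2 (26.8 to 46.0), against 45.0 overall and 38.7 on chromosome 10, the lowest of the others on the same scale; the intervals of both chromosomes include that value. The running numbers themselves came to 138 and 149.6 per Mb of intron on chromosomes 19 and X, and to 160.0 on the lowest other chromosome.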
